A study of Rattus norvegicus with 6 samples.

How the data were processed

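Single cells of the spinal cord were profiled in 6 libraries, per the labels: intact cord, cord 1, 3 and 7 days after crush injury, and cord injected with MPSS or PBS 3 days after injury and collected 2 weeks after injury. The titles of the 2 injected libraries call them re-analyzed. Tissue of a 5-mm section was digested with collagenase and trypsin and strained through 40-µm mesh. The values are UMI counts per gene and cell as deposited, made with Cell Ranger, version 3.0.2 per the submitters' processing notes and 3.1.0 per the file headers of the 2 injected libraries. The labels name kit version 3 beside gel bead kit version 2. How cells were called from droplets is not stated.

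The time-course tables share 28615 gene names, and 77 further names of the intact and day 1 tables were left out. The injected libraries use rat Ensembl identifiers, and the symbols given beside them in the gene files of those libraries were used. The rat gene table of assembly GRCr8 served only to find symbols absent from it. The sets were clustered apart and never compared by level, because the titles call the injected libraries re-analyzed. Gene names also differ between the sets. Names of the Gm, Rik and ENSMUSG forms held 1.79, 0.976, 0.833 and 1.01% of UMIs from intact to day 7. Other symbols absent from the rat table held 7.74, 3.604, 2.87 and 3.63%. Members of a list whose symbol a table lacks are not measured there.

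Cells with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept. Median mitochondrial shares were 2.996, 2.28, 2.64, 2.53, 4.29 and 4.18% for intact, days 1, 3 and 7, PBS and MPSS. Within each set, counts were scaled to 10000 per cell and logged. The 2000 most variable genes gave 30 principal components, 20 neighbours per cell and Leiden clusters at resolution 1. Each cluster took the class of the best of 18 marker lists, or stayed unnamed or unresolved. Phagocytes are the microglia-like, macrophage/monocyte-like and unresolved clusters together. Cells were not aligned across libraries, so clusters can follow libraries as well as cell types.

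Counts were summed over the cells of a class in a library and scaled to CPM. Ratios carry exact binomial intervals, levels exact Poisson intervals and shares exact Clopper-Pearson intervals, all at 95% and for counting error only. With 1 library per group no test between groups was made. Fold against 0 counts is a lower bound from a floor of 3 counts over the group. The 26 gene lists, the markers, the alternatives and the rule for naming genes were fixed before the data were examined. A list needs 5 members with at least 10 UMIs over both sums. Its interval comes from 1000 Poisson draws and its percentile from 10000 random lists drawn in 20 bins of mean expression. By the naming rule, genes are those with the highest and lowest log2 ratio of CPM plus 10: 10 each way in phagocytes, microglia and macrophages, and 4 each way in other classes with at least 50 cells in both libraries. Eligible genes have at least 50 UMIs and 50 CPM where higher, and there at least 0.2 of the CPM of the class with the highest level, a bound against free RNA. Mitochondrial, ribosomal protein and haemoglobin genes, names without a symbol and markers of other classes were left out. List members with the largest ratios are examples. Some genes that these rules name are not reported here. The genes shown by share of cells with a UMI (P2ry12, Arg1, Gpnmb, Il1b, Cd74, S100a9 and Fkbp5) were chosen after the data were seen.

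The interval step was tested on simulated data. Over 12560 simulated genes without a difference, intervals held the true ratio in 96.4%, and over 50 genes doubled in 96%. Of 200 unchanged lists, 5% fell under percentile 2.5 or over 97.5. This covers counting error and not differences between animals. Alternatives were TMM and median-of-ratios scaling, a total without mitochondrial and ribosomal protein genes, other minimum counts, the mean over cells, thinning, other cell filters, doublets left out, 50 components, Leiden resolutions 0.5 and 2, each library clustered alone, each cell named alone, cycling clusters left out and other ranking pseudocounts. Members free of background and sums without the highest cell were added after seeing the data. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, leidenalg 0.10.2, python-igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 for TMM.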

Results

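Gene expression was measured in single cells of the spinal cord with droplet libraries. The series sets an intact cord beside cords collected 1, 3 and 7 days after a crush injury at thoracic level 10, and sets cords injected with MPSS, the labels' name for the injected drug, beside cords injected with its carrier, PBS. MPSS and PBS were injected into the cord 3 days after injury and those cords were collected 2 weeks after injury. Each of the 6 groups holds 1 library, and the labels give 5 animals per condition. The series asks how the immune reaction runs after injury and what the drug does to it. The labels give the intact library the crush treatment too, while its title calls it intact, and the title was followed.

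The intact library held 2757 cells and 9663877 UMIs (counted molecules), with a median of 3090 UMIs per cell. Day 1 held 7360 cells and 50640634 UMIs with a median of 5339.5, day 3 held 9263 cells and 72515788 UMIs with a median of 6648, and day 7 held 7467 cells and 30470794 UMIs with a median of 3617. All of these cells were kept. In the PBS library 1377 of 1513 cells with 16081082 UMIs were kept, and in the MPSS library 2091 of 2339 cells with 23988263 UMIs, at medians of 10292 and 10417 UMIs per cell kept. With 1 library per group no difference has a replicate check, so no test was made. Levels are counts per 1000000 UMIs (CPM) of all cells of a class together, and the range in brackets after a value is its 95% interval, which covers counting error only. A list's median is the median log2 ratio of CPM over its measured members, given with its 95% interval and its percentile among 10000 random lists of like size and expression. Clusters were named from fixed markers, so microglia below means microglia-like cells, and likewise for each class. The labels state rat for every library, but the time-course tables use 3667 symbols absent from the rat gene table and 7654 names of the Gm, Rik and ENSMUSG forms that mouse annotations use. The species of those cells, and with it what the labels state of those animals, is left open here.

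Phagocytes, meaning microglia, macrophages or monocytes and clusters left between these names, made up 30.6% (28.9 to 32.4) of the cells of the intact library and 53.4% (52.2 to 54.5) at day 1, 67.00% (66.03 to 67.96) at day 3 and 65.1% (64.03 to 66.2) at day 7. Microglia were 28.9% (27.2 to 30.6) of intact cells, 0.448% (0.309 to 0.629) at day 1, 30.2% (29.3 to 31.2) at day 3 and 49.9% (48.7 to 51.01) at day 7, while macrophages and monocytes were 1.705% (1.26 to 2.26), 28.9% (27.9 to 29.9), 36.6% (35.6 to 37.5) and 15.2% (14.4 to 16.01). The other 24.1% (23.1 to 25.1) of day 1 cells lay in phagocyte clusters named neither way: their best-scoring class was microglia, but their 10 leading genes held 1 macrophage marker and 0 of microglia. The near absence of microglia at day 1 therefore rests on the naming. These clusters held 1 intact cell, 18 cells of day 3 and 6 cells of day 7. Cycling clusters held 0.376% (0.0777 to 1.096) of the microglia in the intact library, 22.7% (21.2 to 24.3) at day 3 and 1.77% (1.37 to 2.25) at day 7. Among macrophages their share was 0.141% (0.0291 to 0.412) at day 1, 5.64% (4.89 to 6.47) at day 3 and 3.27% (2.31 to 4.47) at day 7.

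Endothelial cells were 41.5% (39.7 to 43.4) of intact cells and 16.5%, 15.6% and 17.05% at days 1, 3 and 7. Neutrophils were 1.85%, 5.39%, 2.26% and 3.86%, and dendritic cells 0.725%, 4.65%, 3.47% and 1.96%. Fibroblasts were 1.45%, 3.03%, 1.57% and 1.69%, oligodendrocyte precursors 1.12%, 1.59%, 2.14% and 3.16%, and pericytes or smooth muscle 0.544%, 0.639%, 1.198% and 1.15%. T and NK cells held 0.508%, 1.11%, 0.367% and 0.536%, and B and plasma cells 0.617%, 1.698%, 0.205% and 0.308%. Ependymal cells were 20.9% (19.4 to 22.4) of intact cells, 3.98% at day 3 and 4.87% at day 7, and 4 cells at day 1. Astrocytes were 0.145%, 11.9%, 2.18% and 0.295%. The day 1 split between ependymal cells and astrocytes rests on the naming: 476 ependymal cells and 407 astrocytes were found there with each library clustered alone, and 495 and 311 with each cell named alone. The tissue was digested and strained, so shares describe the cells recovered.

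**Figure D1:**
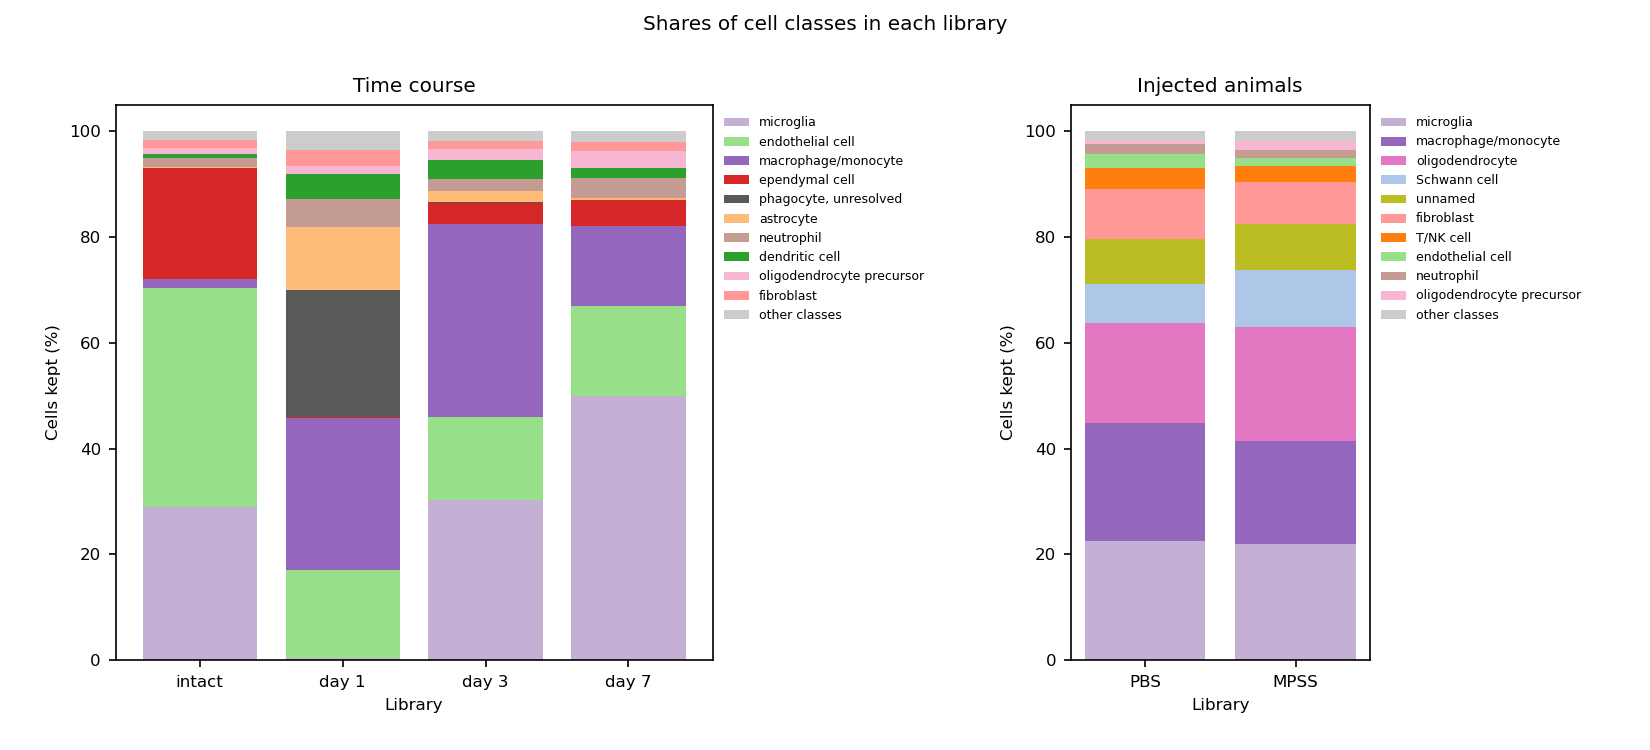
Stacked bars show the percent of cells kept in each class, for the 4 time-course libraries and the 2 injected libraries, 1 library per bar. At day 1, 24.1% of cells were phagocytes unresolved between microglia and macrophages.

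Shares of phagocytes with at least 1 UMI of a gene were compared after each cell was thinned to 1000 UMIs, which left out no cell of these classes. P2ry12, a purinergic receptor of resting microglia, was found in 78.6% (75.7 to 81.3) of intact phagocytes, 3.05% (2.54 to 3.64) at day 1, 23.3% (22.3 to 24.4) at day 3 and 25.7% (24.5 to 26.9) at day 7. Arg1, an arginine-degrading enzyme of wound macrophages, was found in 0.592% (0.192 to 1.38), 48.5% (46.9 to 50.05), 25.1% (24.01 to 26.2) and 0.925% (0.676 to 1.24). Gpnmb, a glycoprotein of lipid-laden phagocytes, was found in 0.237% (0.0287 to 0.852), 3.003% (2.49 to 3.58), 39.1% (37.9 to 40.4) and 26.9% (25.6 to 28.1), and the cytokine Il1b in 4.97% (3.61 to 6.66), 23.99% (22.7 to 25.4), 16.1% (15.2 to 17.1) and 26.2% (25.01 to 27.5). Endothelial cells, which should lack these genes, gave the background: P2ry12 in 3.93%, 0.247%, 1.04% and 1.34%, Arg1 in 0%, 3.78%, 3.52% and 0%, Gpnmb in 0%, 0.0822%, 6.14% and 6.52%, and Il1b in 0.349%, 2.22%, 2.001% and 3.85%. A count of 0 of 1145 intact and of 1273 day 7 endothelial cells allows shares of up to 0.322% and 0.289%. Median depths from intact to day 7 were 3285, 5402, 7576 and 4082 UMIs in phagocytes and 2880, 4486, 4043 and 2486 in endothelial cells. Without thinning, the phagocyte shares were 95.03%, 20.5%, 52.2% and 55.5% for P2ry12, 0.7101%, 64.2%, 45.5% and 2.899% for Arg1, 0.355%, 7.94%, 61.5% and 45.3% for Gpnmb and 10.3%, 47.3%, 38.98% and 46.5% for Il1b. The endothelial shares without thinning were 13.5%, 1.15%, 5.31% and 3.53% for P2ry12, 0.0873%, 16.8%, 11.3% and 0.236% for Arg1, 0%, 0.658%, 23.1% and 16.1% for Gpnmb and 1.48%, 10.3%, 9.11% and 8.64% for Il1b.

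**Figure D2:**
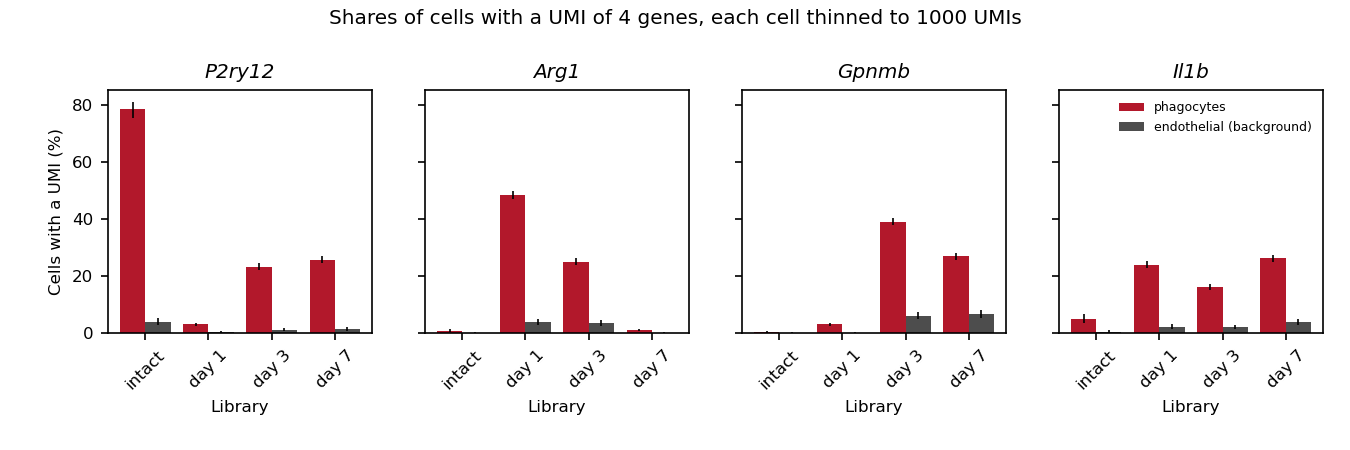
Bars show the percent of cells with at least 1 UMI of each gene after thinning to 1000 UMIs per cell, in phagocytes and in endothelial cells as background, with exact 95% intervals as error bars. P2ry12 was found in 78.6% of intact phagocytes and Arg1 in 48.5% of day 1 phagocytes.

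Day 1 against intact asks what the phagocytes of a freshly crushed cord express. By gene list, phagocytes of day 1 had high levels of chemokines and of glycolysis and hypoxia genes, and low levels of the genes of resting microglia. Spp1, which encodes the secreted phosphoprotein osteopontin, was 265 CPM (247 to 284) in intact and 17495 CPM (17447 to 17543) at day 1, 66.1-fold (61.6 to 70.9) higher, and Arg1 was 39.97 CPM (33.1 to 47.8) and 2424 CPM (2406 to 2442), 60.7-fold (50.7 to 73.2) higher. P2ry12 was 1889 CPM (1840.3 to 1939) in intact and 43.8 CPM (41.4 to 46.2) at day 1, 43.2-fold (40.6 to 45.9) lower. The other genes named by size among the higher were Cebpb by 64.9-fold (54.2 to 78.4), AA467197 by 102-fold (62.8 to 178), Saa3 by 138-fold (70.2 to 321) and Cxcl3 by 57.6-fold (42.2 to 81.1). Also higher were Msr1 by 55.9-fold (39.8 to 81.3), Clec4n by 40.6-fold (28.4 to 60.2), Thbs1 by 23.7-fold (20.3 to 27.97) and Fn1 by 21.5-fold (18.01 to 25.8). Cebpb is a transcription factor of myeloid cells, Saa3 an acute phase protein, Cxcl3 a chemokine for neutrophils, Msr1 and Clec4n are a scavenger and a pattern recognition receptor, and Thbs1 and Fn1 encode the matrix proteins thrombospondin 1 and fibronectin. Single cells held 29.3% of Spp1, 55.8% of Arg1, 37.5% of AA467197, 37.5% of Saa3 and 87.2% of Cxcl3 among the intact UMIs. Among the lower were Slc2a5 by 85.1-fold (66.4 to 111), Gpr34 by 17.2-fold (16.4 to 18.2), Selplg by 15.9-fold (15.3 to 16.4) and Crybb1 by 18.3-fold (16.8 to 19.9). Lower too were Selenop by 13.4-fold (12.97 to 13.9), Sparc by 11.6-fold (11.2 to 12.02), Tmem119 by 10.5-fold (10.1 to 10.97), Hpgd by 11.7-fold (10.9 to 12.6) and Cst3 by 9.06-fold (9.01 to 9.12). Slc2a5 is a fructose transporter, Gpr34 and Tmem119 are microglial surface proteins, Selplg binds selectins, and Cst3 is a secreted protease inhibitor. Spp1 and Cebpb were also at least 2-fold higher, and P2ry12, Selplg and Tmem119 lower, against intact in endothelial cells at each day and in ependymal cells at days 3 and 7. The intact library is not excluded as their cause, nor free RNA for the 3 lower genes, at most at 2.39% of their phagocyte level in intact ependymal cells.

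By list, 16 of 17 measured homeostatic microglia genes were at least 2-fold lower and 0 higher, with a median of -3.101 (-3.17 to -2.99, percentile 0). Of 17 chemokines, 14 were at least 2-fold higher and 0 lower, with a median of 2.48 (2.41 to 2.97, percentile 100), or 2.44 with genes at 0 counts set to the floor of 3 counts. Examples are Ccl7 by 15.5-fold (13.4 to 18.2), Ccl12 by 11.5-fold (10.8 to 12.4) and Ccl6 by 9.93-fold (9.43 to 10.5). The glycolysis and hypoxia list had 14 of 20 members at least 2-fold higher and a median of 1.74 (1.65 to 1.87, percentile 100), with Hilpda by 16.6-fold (13.3 to 20.9), Pkm by 5.996-fold (5.61 to 6.41) and Vegfa by 22.8-fold (10.4 to 62.2). Alternative activation genes had 9 of 16 higher and 2 lower, median 1.77 (0.81 to 2.96, percentile 100), with Il1rn by 32.7-fold (21.1 to 53.5) and Ccl24 by 7.53-fold (6.100 to 9.399). Pro-inflammatory cytokines and enzymes had 9 of 16 higher, median 1.23 (0.97 to 1.82, percentile 100) or 0.91 at the floor, with Ptgs2 by 9.54-fold (6.45 to 14.8), Il1b by 4.504-fold (4.000 to 5.09) and Osm by 4.18-fold (3.59 to 4.89). Disease-associated microglia genes had 11 of 20 higher and 4 lower, median 1.27 (0.96 to 1.31, percentile 100). Interferon response genes had 7 of 20 higher, median 0.79 (0.57 to 0.98, percentile 99.98), with Rsad2 by 8.88-fold (5.45 to 15.6) and Isg15 by 4.04-fold (3.39 to 4.86). Single cells held 33.3% of Vegfa, 29.5% of Ccl24 and 50% of Rsad2 among the intact UMIs. The cell cycle list had 12 of 22 higher, median 1.05 (0.71 to 1.36, percentile 100), led by the replication helicase genes Mcm5 by 11.4-fold (6.33 to 22.8) and Mcm2 by 7.38-fold (4.45 to 13.2).

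Reactive astrocyte genes, with Lgals1 by 9.68-fold (8.82 to 10.6), Cd44 by 11.3-fold (8.77 to 14.8) and Timp1 by at least 68.6-fold, had a median of 1.76 (1.37 to 2.19, percentile 100). Immediate early genes had 8 of 18 at least 2-fold lower, median -0.86 (-0.91 to -0.81, percentile 0.16), with Jun by 4.96-fold (4.82 to 5.096) and Btg2 by 5.05-fold (4.83 to 5.28) lower and Jund by 4.78-fold (4.27 to 5.37) higher. Medians of the other lists were 0.91 (0.54 to 1.10, percentile 99.95) for neutrophil granules and alarmins, 0.74 (0.68 to 0.80, percentile 97.9) for mitochondrial respiration, 0.64 (0.44 to 0.89, percentile 99.1) for lipid handling, -0.49 (-0.94 to 0.33, percentile 14.5) for complement and -0.11 (-0.21 to 0.02, percentile 16.7) for heat shock. They were -0.09 (-0.25 to 0.11, percentile 35.9) for NF-kB targets, -0.22 (-0.45 to 0.01, percentile 28.8) for glucocorticoid receptor targets, -0.07 (-0.27 to 0.18, percentile 78.4) for cholesterol synthesis and 0.20 (0.02 to 0.43, percentile 70.6), or -0.11 with no gene filter, for iron and haem handling. The blood-brain barrier list, -2.21 (-2.44 to -1.97, percentile 0), and the myelin list, -1.24 (-1.46 to -1.12, percentile 0.14), hold genes of other cell types and were not read as phagocyte expression. Over members free of background, a setting added after the data were seen, medians were 2.63 (1.87 to 3.37) for alternative activation, 2.15 (1.58 to 2.58) for cell cycle, 3.01 (2.85 to 3.16) for reactive astrocyte genes, 0.44 (0.41 to 0.48) for neutrophil granules, 0.13 (-0.03 to 0.31) for heat shock, -0.56 (-0.96 to -0.50) for glucocorticoid receptor targets, -0.45 (-0.73 to -0.20) for cholesterol synthesis, 0.53 (0.27 to 0.75) for iron and haem handling, 2.95 (2.45 to 3.31) for chemokines and 0.91 (0.41 to 1.24) for pro-inflammatory genes. The T and NK cell effector list was measured by 5 genes, median 0.74 (-1.01 to 1.74, percentile 82.4), and -1.01 at the floor.

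Within day 1, macrophages lay mostly in cluster 2 and the unresolved cells in clusters 6 and 19, while intact phagocytes lay mostly in the microglial cluster 12. The unresolved cells were set against intact microglia as a comparison added after the data were seen. They too had low levels of homeostatic genes, with a median of -2.66 (-2.72 to -2.54, percentile 0) and 16 of 17 members at least 2-fold lower, and high levels of chemokines, 2.43 (2.07 to 2.85, percentile 100), glycolysis genes, 1.25 (1.13 to 1.39, percentile 100), and cell cycle genes, 1.36 (1.001 to 1.75, percentile 100). P2ry12 was 32.7-fold (30.7 to 34.9) lower there and Spp1 118-fold (106 to 131) higher. Single cells held 65.6% of Spp1 among the intact UMIs. Their chemokine median was 2.40 with genes at 0 counts at the floor, and that of the interferon response 0.06 (-0.29 to 0.28, percentile 83.6). Scaling by TMM in place of the total raised all day 1 log2 ratios of phagocytes by 0.29 and those of the unresolved cells by 0.21. The phagocyte medians whose sign then turned were glucocorticoid receptor targets, NF-kB targets, heat shock, cholesterol synthesis and lysosome. The lysosome median was -0.08 (-0.20 to 0.00, percentile 11.8) before that.

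Day 3 against intact asks the same in the library with the largest phagocyte share. By gene list, phagocytes of day 3 had high levels of disease-associated, lipid handling, lysosome and cell cycle genes, and low levels of the genes of resting microglia. Gpnmb was 0.999 CPM (0.206 to 2.92) in intact, from 3 UMIs, and 1680.2 CPM (1669 to 1691) at day 3, 1681-fold (575 to 8154) higher. Spp1 was 26542 CPM (26499 to 26585) at day 3, 100.2-fold (93.5 to 108) higher. Cst3 was 75575 CPM (75264 to 75886) in intact and 6645 CPM (6623 to 6666) at day 3, 11.4-fold (11.3 to 11.4) lower. Also among the higher were Fabp5 by 159.9-fold (126 to 207), Fabp4 by 354-fold (63.5 to 13975), Apoc1 by 77.1-fold (33.03 to 238) and Plin2 by 14.5-fold (12.7 to 16.8), genes of fatty acid binding, lipoproteins and lipid droplets, the galectins Lgals3 by 21.02-fold (19.2 to 23.03) and Lgals1 by 15.9-fold (14.4 to 17.4), and Arg1 by 24.6-fold (20.6 to 29.7) and Cebpb by 13.7-fold (11.5 to 16.6). Single cells held 29.3% of Spp1 and 55.8% of Arg1 among the intact UMIs. Fabp4 rested on 1 intact UMI. The lower were Lag3 by 14.97-fold (13.7 to 16.3), Crybb1 by 10.1-fold (9.49 to 10.7), Adgrg1 by 12.1-fold (10.8 to 13.6), P2ry13 by 8.76-fold (8.104 to 9.47) and Slc2a5 by 9.78-fold (8.86 to 10.8). Lower too were Adap2os by 7.73-fold (7.21 to 8.28), Selplg by 6.65-fold (6.49 to 6.82), Tmem119 by 6.76-fold (6.54 to 6.99) and Arhgap5 by 8.78-fold (7.97 to 9.67). Lag3 is an inhibitory immune receptor, Adgrg1 an adhesion G protein-coupled receptor and P2ry13 a purinergic receptor.

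All 17 of 17 measured homeostatic genes were at least 2-fold lower, median -2.40 (-2.46 to -2.31, percentile 0). Disease-associated microglia genes had 15 of 20 higher, median 1.66 (1.55 to 1.94, percentile 100), and lipid handling 13 of 20, median 1.49 (1.36 to 1.69, percentile 100). The cell cycle list had 16 of 22 higher, median 2.13 (1.76 to 2.59, percentile 100), with Pclaf by 22.7-fold (12.3 to 47.4), Ube2c by 15.9-fold (9.27 to 29.8) and Birc5 by 12.3-fold (7.76 to 20.7). Single cells held 61.5% of Ube2c and 27.8% of Birc5 among the intact UMIs. Lysosome genes had 12 of 24 higher, median 0.92 (0.88 to 0.95, percentile 100), with Lamp1 by 11.1-fold (10.1 to 12.2) and Ctsb by 4.36-fold (4.25 to 4.48), and glycolysis 10 of 20, median 0.92 (0.80 to 1.15, percentile 100). Chemokines had a median of 0.79 (0.59 to 0.88, percentile 99.95), with Ccl7 by 7.34-fold (6.31 to 8.59) and Pf4 by 4.59-fold (4.21 to 5.02), alternative activation 0.96 (0.42 to 2.14, percentile 100), with 7 of 15 at least 2-fold higher and 6 lower, and pro-inflammatory genes 0.38 (0.08 to 0.45, percentile 97.9), or -0.05 at the floor. Over members free of background the medians were 2.41 (1.02 to 3.13) for alternative activation, 2.48 (1.63 to 2.87) for lipid handling, 2.13 (1.98 to 2.16) for disease-associated and -0.39 (-0.51 to -0.26) for pro-inflammatory genes. Cholesterol synthesis had 11 of 16 lower, median -1.31 (-1.40 to -0.97, percentile 0.69), with Insig1 by 4.78-fold (4.097 to 5.55) and Msmo1 by 2.54-fold (2.11 to 3.04). Immediate early genes, -1.10 (-1.14 to -1.06, percentile 0.02), and heat shock genes, -0.87 (-0.96 to -0.81, percentile 0.845), were also low, with Jun by 5.01-fold (4.88 to 5.14) and Hspa1a by 4.68-fold (4.505 to 4.85). Mitochondrial respiration had a median of 0.62 (0.57 to 0.67, percentile 99.7). The interferon response median was -0.53 (-0.73 to -0.40, percentile 50.03), or 0.00397 with median-of-ratios scaling, and that of MHC class II presentation -0.87 (-0.89 to -0.76, percentile 11.1) over 5 genes, or -0.87 (-0.89 to -0.79, percentile 2.85) over 11 with the mouse names of the class II genes, an addition made after the data were seen.

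Microglia alone could be compared at day 3, mostly of clusters 0, 5 and the cycling cluster 13, with those of the intact cord, mostly of cluster 12. By gene list, their levels of cell cycle and disease-associated genes were high and those of homeostatic and heat shock genes low. The higher were Apoc1 by 347-fold (96.1 to 2869), Cebpb by 14.3-fold (11.6 to 17.8), Cxcl2 by 11.6-fold (10.2 to 13.4), Gnas by 10.98-fold (9.996 to 12.1) and Timp2 by 10.4-fold (9.24 to 11.9). Also higher were Dusp2 by 17.95-fold (12.4 to 27.05), Igf1 by 22.5-fold (14.04 to 38.7), Lamp1 by 9.58-fold (8.66 to 10.6), Pclaf by 32.8-fold (17.2 to 71.7) and Bri3 by 9.94-fold (8.46 to 11.8). Single cells held 41.2% of Igf1 among the intact UMIs. Apoc1 rested on 2 intact UMIs. Cebpb, Cxcl2, Gnas, Lamp1 and Bri3 were higher and Gstp1 lower in phagocytes, endothelial and ependymal cells, so the intact library is not excluded as their cause. Cxcl2 is a chemokine for neutrophils, Timp2 an inhibitor of metalloproteinases, Igf1 a growth factor and Pclaf a partner of the replication clamp. The lower were Cst3 by 6.12-fold (6.09 to 6.15), Lag3 by 7.09-fold (6.49 to 7.75), Hspa1a by 5.99-fold (5.72 to 6.26), Adap2os by 5.88-fold (5.45 to 6.34) and Malat1 by 5.27-fold (5.22 to 5.31). Lower too were Adap2 by 5.499-fold (5.03 to 6.01), Adgrg1 by 5.82-fold (5.17 to 6.54), Gstp1 by 8.78-fold (7.18 to 10.7), Gng10 by 6.24-fold (5.42 to 7.19) and Crybb1 by 4.72-fold (4.44 to 5.01). Hspa1a is an inducible chaperone and Malat1 a nuclear RNA. Gstp1 and Hspa1a have close relatives that can share reads, so their values are uncertain. Homeostatic genes had 9 of 17 at least 2-fold lower, median -1.38 (-1.43 to -1.33, percentile 0), disease-associated genes 15 of 20 higher, median 1.66 (1.63 to 1.96, percentile 100), and cell cycle genes 19 of 22 higher, median 2.65 (2.33 to 3.08, percentile 100). The interferon response list was low at -0.83 (-1.06 to -0.60, percentile 4.25), with Herc6 by 4.17-fold (2.98 to 5.78) and Irf9 by 2.100-fold (1.71 to 2.57), and the heat shock list at -1.04 (-1.11 to -0.97, percentile 0.04). Pro-inflammatory genes had a median of 1.16 (1.01 to 1.27, percentile 99.99), or 0.30 at the floor, and chemokines 1.32 (0.65 to 1.52, percentile 100), or 0.53 (0.49 to 0.55) over members free of background.

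Day 7 against intact asks which differences remain. By gene list, day 7 phagocytes had high levels of disease-associated and lipid handling genes. As named, macrophages and monocytes were 47 of 845 intact phagocytes and 1133 of 4863 at day 7, so the mix differed too. Arg1 was not higher than in intact, at 19.7 against 39.97 CPM. Its log2 ratio was 4.66 with each library clustered alone and 0.0496 without the highest cell. Single cells held 29.3% of Spp1 and 55.8% of Arg1 among the intact UMIs. Apoe, the lipid carrier, was 3374 CPM (3308 to 3440.0) in intact and 89067 CPM (88944 to 89191) at day 7, 26.4-fold (25.9 to 26.9) higher, and Gpnmb 1331 CPM (1316 to 1346) at day 7, 1332-fold (456 to 6458) higher. The others named among the higher were Apoc1 by 556-fold (238 to 1712), Spp1 by 39.6-fold (36.97 to 42.5), Fabp5 by 43.00-fold (33.8 to 55.6) and Cst7 by 33.9-fold (24.02 to 49.6). Also higher were Cebpb by 20.6-fold (17.2 to 24.9), Apoc4 by 58.3-fold (30.7 to 128), Igf1 by 23.1-fold (17.2 to 31.8) and Timp2 by 13.6-fold (12.2 to 15.3). Cst7 is a protease inhibitor of activated microglia. The lower were Slc2a5 by 12.2-fold (10.7 to 13.9), P2ry12 by 7.03-fold (6.78 to 7.29), Klk8 by 7.38-fold (6.62 to 8.24), Crybb1 by 6.26-fold (5.86 to 6.68) and Lrba by 9.43-fold (8.04 to 11.1). Lower too were Selplg by 5.62-fold (5.47 to 5.78), Adap2 by 6.17-fold (5.63 to 6.77), P2ry13 by 5.93-fold (5.45 to 6.46), Tmem119 by 5.04-fold (4.85 to 5.23) and Adap2os by 5.42-fold (5.02 to 5.85). Homeostatic genes had 13 of 17 at least 2-fold lower, median -1.68 (-1.73 to -1.63, percentile 0). Disease-associated genes had 14 of 20 higher, median 2.41 (2.27 to 2.80, percentile 100), lipid handling 12 of 20, median 1.77 (1.60 to 2.06, percentile 100), or 2.33 (1.93 to 2.74) over members free of background, and lysosome 9 of 24, median 0.76 (0.71 to 0.80, percentile 100). Of 20 interferon response genes 8 were higher, median 0.61 (0.40 to 0.86, percentile 100), with Bst2 by 2.88-fold (2.64 to 3.13) and Isg15 by 2.204-fold (1.84 to 2.66). Chemokines had a median of 0.54 (0.49 to 0.59, percentile 99.99), pro-inflammatory genes 0.92 (0.75 to 1.04, percentile 100) or 0.33 at the floor, glycolysis 0.05 (-0.13 to 0.19, percentile 98.3) and alternative activation -0.20 (-0.56 to 0.33, percentile 97.3). Heat shock genes were low, -0.93 (-0.98 to -0.79, percentile 0.37), and cholesterol synthesis was -0.91 (-1.09 to -0.74, percentile 17.6). TMM scaling raised the phagocyte log2 ratios by 0.51 at day 3 and 0.61 at day 7. With it the medians whose sign turned were neutrophil granules and alarmins and reactive astrocyte genes at day 3 and alternative activation and resolution, MHC class II presentation, complement, glucocorticoid receptor targets, neutrophil granules and alarmins, immediate early genes, reactive astrocyte genes, T and NK cell effector genes and iron and haem handling at day 7. The day 7 medians of MHC class II presentation, glucocorticoid receptor targets, immediate early genes and iron and haem handling were -0.51, -0.51, -0.38 and -0.30 before that.

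Microglia of day 7, mostly of clusters 0, 5 and 16, were set against those of the intact cord, mostly of cluster 12. The lists of disease-associated, lipid handling and interferon response genes were high. Cluster 16, led by interferon response genes, held 0.627%, 0.928% and 13.5% of intact, day 3 and day 7 microglia. The higher were Apoc1 by 1619-fold (448 to 13373), Apoe by 37.3-fold (36.3 to 38.2), Igf1 by 62.1-fold (38.7 to 107), Cst7 by 44.4-fold (31.3 to 65.4) and Cebpb by 26.8-fold (21.7 to 33.4). Also higher were Timp2 by 17.7-fold (15.6 to 20.04), Apoc4 by 67.3-fold (34.1 to 156), Cxcl2 by 16.5-fold (14.4 to 18.9), Dusp2 by 24.2-fold (16.7 to 36.5) and Saa3 by 261-fold (46.8 to 10321). Single cells held 41.2% of Igf1 among the intact UMIs. Apoc1 rested on 2 intact UMIs and Saa3 rested on 1 intact UMI. The lower were Slc2a5 by 9.55-fold (8.39 to 10.9), P2ry12 by 5.64-fold (5.43 to 5.85), Lrba by 7.48-fold (6.36 to 8.81), Adap2 by 5.53-fold (5.02 to 6.09) and Klk8 by 5.71-fold (5.12 to 6.37). Lower too were Crybb1 by 4.87-fold (4.56 to 5.21), Selplg by 4.59-fold (4.46 to 4.72), P2ry13 by 5.04-fold (4.62 to 5.504), Adap2os by 4.88-fold (4.504 to 5.28) and Txnip by 5.04-fold (4.58 to 5.54). Disease-associated genes had 15 of 20 higher, median 2.70 (2.43 to 3.35, percentile 100), and lipid handling 12 of 20, median 2.40 (2.23 to 2.57, percentile 100), or 1.87 at the floor. Over members free of background these medians were 1.82 (1.78 to 1.87) and 1.72 (1.53 to 1.97). Homeostatic genes had 10 of 17 lower, median -1.37 (-1.45 to -1.32, percentile 0). The interferon response list had 11 of 20 higher, median 1.12 (0.84 to 1.33, percentile 100), with Isg15 by 3.26-fold (2.66 to 4.04), Bst2 by 2.56-fold (2.34 to 2.81) and Irf7 by 3.104-fold (2.41 to 4.07). Cell cycle genes had a median of 0.77 (0.35 to 0.93, percentile 100), and of -0.12 over the members free of background. TMM scaling raised the microglial log2 ratios by 0.39 at day 3 and 0.58 at day 7, where the sign turned for MHC class II presentation, glucocorticoid receptor targets, neutrophil granules and alarmins, immediate early genes and iron and haem handling.

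Endothelial cells lay mostly in cluster 9 in the intact cord, in cluster 8 at day 1 and in cluster 1 at days 3 and 7, so different clusters were compared. At day 1 genes of vessel growth and activation were high and barrier genes low, and both list medians were closer to 0 at days 3 and 7. Igfbp7, a secreted factor of activated vessels, was 309 CPM (292 to 327) in intact and 10737 CPM (10662 to 10812) at day 1, 34.7-fold (32.9 to 36.8) higher, and 18.3-fold (17.3 to 19.4) and 10.4-fold (9.84 to 11.1) higher at days 3 and 7. Apln, the ligand apelin made by endothelial tip cells, was higher by 224-fold (122 to 468) at day 1 and 29.5-fold (15.9 to 61.8) at day 3. Also higher at day 1 were Igfbp4 by 324-fold (164 to 750.1) and Tubb6 by 66.3-fold (48.6 to 92.9). The gene Itm2a, of the barrier list, was 7124 CPM (7042 to 7207) in intact and 611 CPM (594 to 629.6) at day 1, 11.7-fold (11.3 to 12.03) lower, beside Ptn by 15.1-fold (14.2 to 16.1), Pltp by 11.6-fold (11.04 to 12.2) and Slc22a8 by 12.97-fold (11.4 to 14.9). The transcription factor Jund was higher by 6.996-fold (6.57 to 7.46) at day 3 and 14.4-fold (13.5 to 15.4) at day 7, Tmem238 by 16.8-fold (10.5 to 28.5) and 20.5-fold (12.8 to 35.00), and at day 7 the flow-induced Klf2 by 7.22-fold (6.94 to 7.51). Lower at day 3 were Gstp1 by 7.83-fold (6.52 to 9.45), Ftl1-ps1 by 5.31-fold (4.56 to 6.204), Chek2 by 5.96-fold (4.82 to 7.43) and Ccdc85b by 3.87-fold (3.55 to 4.21), and at day 7 Rpl15-ps6 by 3.51-fold (2.898 to 4.28), Chek2 by 3.400-fold (2.69 to 4.34) and Ceacam1 by 2.92-fold (2.45 to 3.48). Names with a ps ending are pseudogenes, which can share reads with their parent genes, so those values are uncertain.

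The endothelial activation and angiogenesis list had 9 of 16 members at least 2-fold higher at day 1, median 3.32 (2.81 to 3.40, percentile 100) or 2.44 at the floor, 11 of 16 at day 3, median 1.92 (1.66 to 2.22, percentile 100), and 5 of 14 at day 7, median 0.73 (0.42 to 0.84, percentile 100). Examples at day 1 are Lrg1 by 27.98-fold (24.2 to 32.6), Pgf by 74.3-fold (43.3 to 139.8) and Ackr1 by 30.8-fold (22.8 to 42.6). Single cells held 69.2% of Pgf and 58.1% of Ackr1 among the intact UMIs. The blood-brain barrier list had 11 of 15 at least 2-fold lower at day 1, median -1.68 (-1.75 to -1.59, percentile 0), with Tfrc by 6.705-fold (5.74 to 7.86), Slc7a5 by 5.57-fold (5.11 to 6.07) and Mfsd2a by 4.600-fold (4.14 to 5.11), and medians of -0.24 (-0.34 to -0.22, percentile 14.3) and -0.22 (-0.25 to -0.20, percentile 4.41) at days 3 and 7. Immediate early genes were -1.22 (-1.24 to -1.11, percentile 0), -0.52 (-0.56 to -0.46, percentile 0.11) and 0.31 (0.28 to 0.39, percentile 99.7), with Jund by 5.95-fold (5.58 to 6.34) and Klf2 by 4.24-fold (4.08 to 4.41) higher and Nr4a1 by 5.12-fold (4.54 to 5.79) and Btg2 by 3.43-fold (3.23 to 3.64) lower at day 1. Cholesterol synthesis was 0.60 (0.46 to 0.76, percentile 99.6), -0.58 (-0.81 to -0.46, percentile 0.53) and -0.66 (-0.86 to -0.49, percentile 0.1), with Sqle by 3.01-fold (2.13 to 4.36) and Idi1 by 1.898-fold (1.49 to 2.44) higher at day 1 and Insig1 by 3.63-fold (3.01 to 4.39) and Msmo1 by 2.14-fold (1.77 to 2.602) lower at day 3. Glycolysis and hypoxia was 1.04 (0.85 to 1.16, percentile 99.99), 0.07 (-0.14 to 0.13, percentile 87.95) and -0.34 (-0.39 to -0.25, percentile 3.31), and the interferon response -0.86 (-0.99 to -0.69, percentile 0), -0.89 (-1.02 to -0.82, percentile 0) and 0.13 (0.00 to 0.26, percentile 99.5), with Rtp4 by 2.91-fold (2.54 to 3.33) and Ifit1 by 2.92-fold (2.55 to 3.36) lower at day 1. Matrix genes had medians of 1.54 (1.27 to 2.24, percentile 100), 1.16 (1.07 to 1.73, percentile 100) and 0.99 (0.44 to 1.32, percentile 100), or 1.31 and 1.16 at days 1 and 3 with the floor, with Timp1 by 149.9-fold (64.1 to 462), Col4a2 by 6.17-fold (5.64 to 6.76) and Col4a1 by 5.22-fold (4.84 to 5.64) higher at day 1. Microglia markers reached a median of 2.22%, 5.11%, 4.13% and 4.23% of their phagocyte level in endothelial cells from intact to day 7. Lists of phagocyte genes were therefore not read in this class. TMM scaling raised the endothelial log2 ratios by 0.17 at day 3 and 0.18 at day 7, where the sign turned for glucocorticoid receptor targets, heat shock and myelin. Igfbp7 and Jund were higher and Gstp1 and Rpl15-ps6 lower in phagocytes, endothelial and ependymal cells, so the intact library is not excluded as their cause. Over members free of such background the medians of the matrix list were 0.73, 0.90 and 0.12, and those of glycolysis 0.61 (0.53 to 0.68), -0.17 (-0.21 to -0.09) and -0.36 (-0.43 to -0.31).

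**Figure D3:**
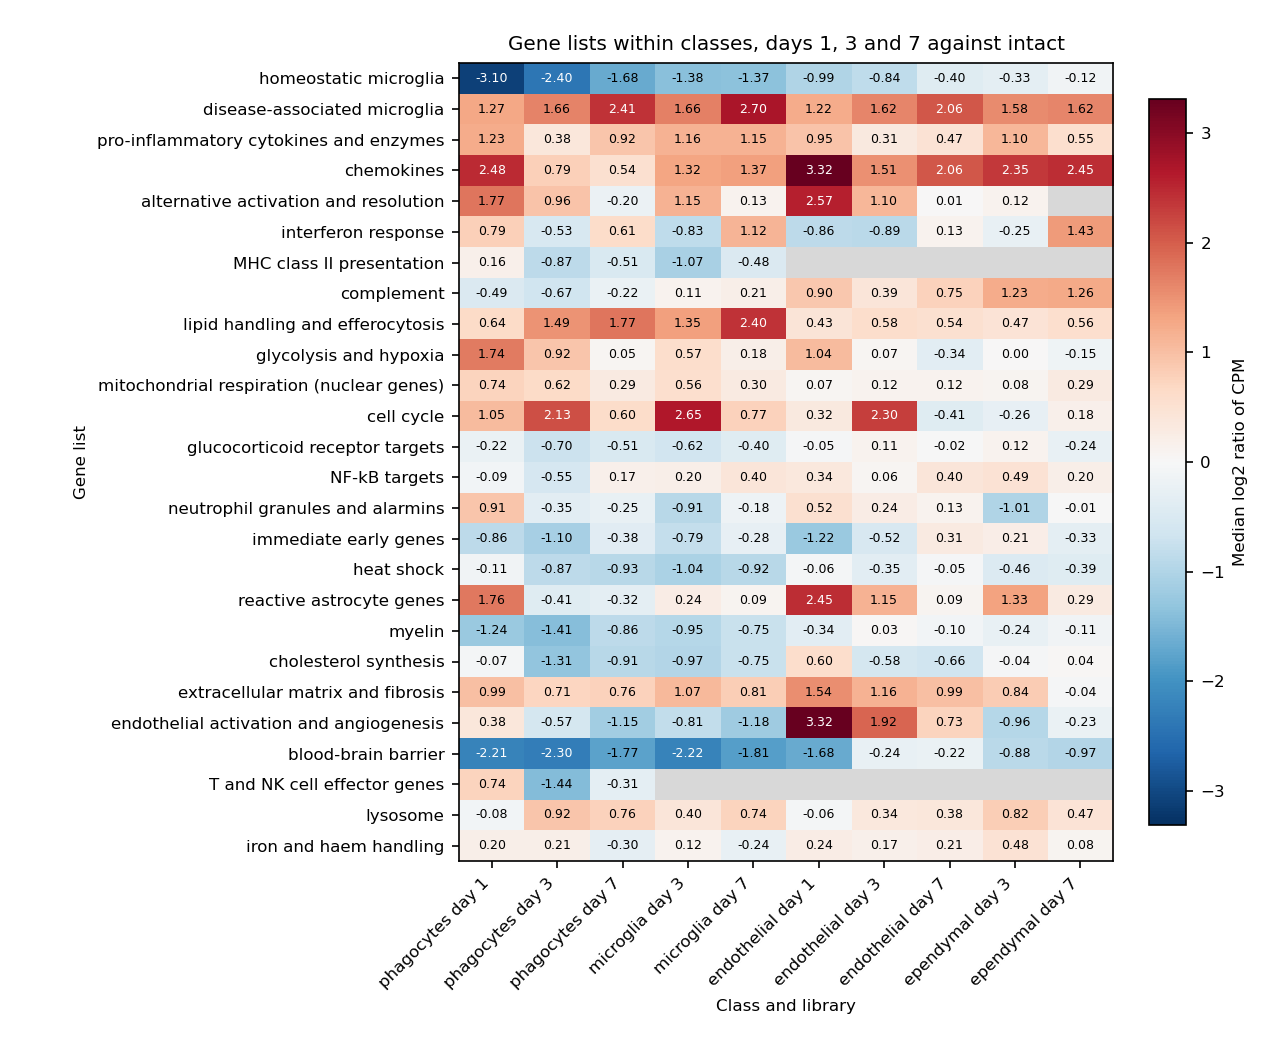
Each cell of the grid is the median log2 ratio of CPM of a gene list (lines of the grid) in 1 class at 1 day against the same class in the intact library. Red is higher and blue lower than intact, grey has under 5 measured members, and homeostatic microglia genes were lower in phagocytes at days 1, 3 and 7, at -3.101, -2.40 and -1.68.

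Ependymal cells, the ciliated lining of the central canal, were compared at days 3 and 7, all from cluster 7. Astrocyte-type reactive genes were high at day 3, and interferon response genes at day 7. Jund was higher by 10.03-fold (8.78 to 11.5) at day 3 and 11.2-fold (9.77 to 12.9) at day 7, Ccdc74a by 10.2-fold (7.43 to 14.3) and 10.2-fold (7.35 to 14.3), Ptov1 by 8.98-fold (6.89 to 11.9) and 8.46-fold (6.43 to 11.3), and Cebpb by 8.43-fold (6.38 to 11.3) at day 7. Lower at day 3 were Gstp1 by 5.48-fold (3.94 to 7.81), Apod by 8.16-fold (4.42 to 16.7), Pgk1 by 4.94-fold (3.22 to 7.92) and Rpl15-ps6 by 4.66-fold (2.999 to 7.56), and at day 7 Apod by 16.3-fold (6.21 to 60.6), Rpl15-ps6 by 2.99-fold (1.97 to 4.71), Rpl13-ps3 by 2.64-fold (2.01 to 3.53) and Impact by 2.74-fold (1.95 to 3.94). Single cells held 74.6% of Apod among the intact UMIs. Serpina3n rested on 2 intact UMIs. The reactive astrocyte list had 11 of 19 at least 2-fold higher at day 3, median 1.33 (1.10 to 1.48, percentile 100), with Lgals1 by 11.1-fold (7.83 to 16.2), Gfap by 6.95-fold (5.41 to 9.03), Serpina3n by 41.05-fold (10.8 to 347) and Hspb1 by 2.63-fold (2.38 to 2.91), and a median of 0.29 (0.21 to 0.68, percentile 98.7) at day 7. Over the 11 members free of background the day 3 median was 1.11 (0.96 to 1.41), with 6 at least 2-fold higher. Jund, Ptov1, Cebpb and Lgals1 were higher and Gstp1, Rpl15-ps6 and Rpl13-ps3 lower in phagocytes, endothelial and ependymal cells, so the intact library is not excluded as their cause, nor free RNA from phagocytes for Lgals1. The interferon response list was -0.25 (-0.57 to 0.22, percentile 26.4) at day 3 and 1.43 (0.84 to 1.71, percentile 100) at day 7, when 10 of 16 were at least 2-fold higher, with Ifit1 by 7.796-fold (4.26 to 15.2) and Ifi27 by 3.46-fold (2.48 to 4.85). Over members free of background the day 7 median was 0.66. Immediate early genes were 0.21 (0.14 to 0.28, percentile 91.7) and -0.33 (-0.50 to -0.27, percentile 0.02), heat shock genes -0.46 (-0.61 to -0.37, percentile 0.035) and -0.39 (-0.46 to -0.28, percentile 0.02).

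Neutrophils, from clusters 14 and 20, the second of which was cycling, were compared with 51 intact cells. The median of the granule list was low at days 1 and 3, with members going both ways. At day 1 Cxcl3 was higher by at least 36.9-fold and Saa3 by at least 13.9-fold, both from 0 intact UMIs against the floor of 3 counts, and Cebpb by 18.6-fold (13.3 to 26.9) and Ybx1 by 12.6-fold (7.97 to 21.3). Lower were Ly6g by 7.44-fold (6.21 to 8.91), Tmcc1 by 4.06-fold (3.07 to 5.32), Chil1 by 3.86-fold (3.08 to 4.81) and Hdc by 3.48-fold (2.98 to 4.05). Cebpb and Ybx1 were higher against intact in phagocytes, endothelial and ependymal cells too, with the same limit. At day 3 the higher were Apoe by 34.2-fold (27.8 to 42.5), Igfbp6 by 44.7-fold (12.2 to 371), Ccrl2 by 28.96-fold (11.2 to 107) and Clec4n by 28.9-fold (11.2 to 107), and the lower Ltf by 4.72-fold (4.33 to 5.15), Orm1 by 5.52-fold (3.401 to 9.16), Mrgpra2b by 5.21-fold (3.38 to 8.18) and Retnlg by 4.48-fold (4.26 to 4.71). Single cells held 26.4% of Apoe and 50% of Clec4n among the intact UMIs. Igfbp6 rested on 2 intact UMIs. At day 7 the mast cell and basophil proteases Prss34, at least 44.8-fold, and Mcpt8, at least 32.2-fold, and the phosphatase Dusp2, at least 5.297-fold, were higher against 0 intact UMIs, and the granule protease Elane by 7.196-fold (4.98 to 10.8). Single cells held 34.5% of Elane among the intact UMIs, and 60.9% of Prss34, 56.2% of Mcpt8 and 33.00% of Elane among the day 7 UMIs. With each cell named alone the log2 ratio of Mcpt8 was -0.96. The lower were Lrg1 by 3.01-fold (2.49 to 3.65), Mrgpra2b by 2.76-fold (1.99 to 3.79), Stx11 by 2.73-fold (1.89 to 3.93) and Samhd1 by 2.58-fold (1.805 to 3.65). The granule and alarmin list had 9 of 20 at least 2-fold lower and 4 higher at day 1, median -0.96 (-1.02 to -0.85, percentile 0), with Ngp by 2.64-fold (2.59 to 2.699), a marker of the class, lower, and Elane by 7.21-fold (5.01 to 10.8) and Ctsg by 7.99-fold (4.03 to 18.6) higher. Single cells held 62.5% of Ctsg among the intact UMIs. Its medians were -1.39 (-1.40 to -1.22, percentile 0) and -0.29 (-0.37 to -0.18, percentile 0.54) at days 3 and 7, and Elane by 5.69-fold (3.903 to 8.59) and Mpo by 5.02-fold (2.72 to 10.3) were higher at day 3. Single cells held 45.5% of Mpo among the intact UMIs, and 56.3% of Elane and 59.7% of Mpo among the day 3 UMIs. The sign of their log2 ratios turned, to -0.00251 for Elane with thinning and -0.13 for Mpo with the mean over cells, so no direction was read for them. Cell cycle genes were 0.76 (0.63 to 1.15, percentile 91.7), -0.72 (-1.19 to -0.47, percentile 0) and 0.49 (0.26 to 0.77, percentile 99.5). Cycling clusters held 17.6% (8.401 to 30.9) of intact neutrophils and 31.99% (27.4 to 36.8), 5.26% (2.66 to 9.22) and 29.5% (24.3 to 35.1) at days 1, 3 and 7. Microglia markers reached 2.68%, 18.4%, 11.3% and 10.6% of their phagocyte level from intact to day 7. Phagocyte lists were thus not read, and background is open for Apoe, Clec4n, Cxcl3 and Saa3. TMM scaling moved the log2 ratios by -0.35 at day 1 and -0.48 at day 3, where the sign turned for homeostatic microglia, glucocorticoid receptor targets and myelin and for homeostatic microglia and glycolysis and hypoxia.

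MPSS against PBS asks what the injected drug does to the cells of the injured cord. Most classes had shares with overlapping intervals, and Schwann cells were the exception. Phagocytes were 44.9% (42.2 to 47.6) of cells with PBS and 41.4% (39.3 to 43.6) with MPSS, microglia 22.5% (20.3 to 24.8) and 21.9% (20.1 to 23.7), and macrophages and monocytes 22.4% (20.2 to 24.7) and 19.6% (17.9 to 21.3). Oligodendrocytes were 18.95% (16.9 to 21.1) and 21.7% (19.9 to 23.5), Schwann cells 7.26% (5.95 to 8.76) and 10.7% (9.37 to 12.1), fibroblasts 9.296% (7.81 to 10.95) and 7.94% (6.82 to 9.18), and T and NK cells 4.07% (3.09 to 5.25) and 3.06% (2.36 to 3.89). Neutrophils were 1.82% and 1.53%, endothelial cells 2.61% and 1.53%, oligodendrocyte precursors 0.799% and 1.63%, and pericytes or smooth muscle 0.944% and 0.861%. B and plasma cells were 0.726% and 0.956%, and clusters 5 and 15 stayed unnamed with 8.64% and 8.75%. Phagocyte shares with each library clustered alone were 47.6% and 38.3%.

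In phagocytes, genes of the interferon response were higher with MPSS and genes of MHC class II presentation and chemokines lower, all by small sizes. The interferon response list had a median of 0.39 (0.30 to 0.52, percentile 100), with 3 of 22 at least 2-fold higher and 0 lower, and Ifit3 by 2.51-fold (1.96 to 3.24), Rtp4 by 1.75-fold (1.49 to 2.07) and Mx2 by 1.63-fold (1.38 to 1.94). MHC class II presentation was -0.37 (-0.50 to -0.20, percentile 0.04), with 0 of 10 at least 2-fold lower, and Ctss by 1.898-fold (1.82 to 1.98), RT1-Db1 by 1.54-fold (1.41 to 1.67), RT1-Da by 1.46-fold (1.36 to 1.57) and Cd74 by 1.41-fold (1.35 to 1.48). With each library clustered alone the median was -2.62. Glucocorticoid receptor targets had a median of -0.13 (-0.27 to -0.08, percentile 2.94), with 1 of 20 at least 2-fold higher and 1 lower. Among them Il1r2 by 4.697-fold (2.89 to 8.06) and Fkbp5 by 1.997-fold (1.64 to 2.44) were higher and Mt1 by 1.31-fold (1.22 to 1.41) lower. Fkbp5 was found in 1.14% (0.4596 to 2.33) of PBS and 3.94% (2.74 to 5.46) of MPSS phagocytes at 1000 UMIs, and in 1.75% and 3.83% of oligodendrocytes. Chemokines were -0.22 (-0.28 to -0.16, percentile 0), NF-kB targets -0.19 (-0.30 to -0.10, percentile 0.16), complement -0.17 (-0.31 to -0.11, percentile 0.24), neutrophil granules and alarmins, open to free RNA of neutrophils, -0.47 (-0.51 to -0.44, percentile 0), homeostatic microglia -0.11 (-0.18 to -0.03, percentile 3.77) and disease-associated microglia -0.11 (-0.12 to -0.06, percentile 0.27). Pro-inflammatory genes were -0.06 (-0.15 to 0.03, percentile 17.6) and glycolysis -0.16 (-0.24 to -0.10, percentile 0.47).

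Of the genes named by size, the higher ones given here were of modest ratio, at most 3.05-fold. Cyp2d3 was 21.5 CPM (18.6 to 24.8) with PBS and 65.6 CPM (61.2 to 70.2) with MPSS, 3.05-fold (2.603 to 3.58) higher. The others were Lyve1 by 2.42-fold (2.05 to 2.85), Taf10 by 2.02-fold (1.86 to 2.21), Tgfb1 by 1.89-fold (1.74 to 2.06) and Ly6e by 1.72-fold (1.58 to 1.88). Also higher were Snx20 by 1.81-fold (1.598 to 2.06), Tmem165 by 1.68-fold (1.47 to 1.91), Marchf2 by 1.59-fold (1.43 to 1.77) and Sdf2l1 by 1.505-fold (1.44 to 1.57). With thinning the log2 ratio of Tmem165 was -0.54. Lyve1 is a hyaluronan receptor of resident macrophages, Tgfb1 a suppressive cytokine and Ly6e an interferon-induced membrane protein. Serping1, the C1 inhibitor, was 259.6 CPM (249 to 270.4) and 53.1 CPM (49.2 to 57.3), 4.89-fold (4.48 to 5.33) lower, beside Cxcl13 by 3.37-fold (2.87 to 3.96), Fam111a by 2.74-fold (2.42 to 3.11), Fabp4 by 2.04-fold (1.96 to 2.12), Fxyd2 by 2.19-fold (1.98 to 2.43) and Ctss by 1.898-fold (1.82 to 1.98). Mt3 was lower by 12.3-fold (9.54 to 16.2). Single cells held 33.7% of Mt3 and 57.5% of Cxcl13 among the PBS UMIs, and 32.9% of Cxcl13 among the MPSS UMIs. The defensin genes RatNP-3b, at least 528-fold lower, Defa5, at least 343-fold, and Np4, 68.3-fold (36.8 to 143), came almost wholly from a single PBS cell, so no class difference was read from them. In microglia, clusters 0, 2 and 14, the median of MHC class II presentation was -0.90 (-1.03 to -0.59, percentile 0) and that of the interferon response 0.31 (0.20 to 0.49, percentile 100). The lower there were Fam111a by 5.59-fold (4.64 to 6.76), Cd74 by 2.36-fold (2.17 to 2.58), RT1-Db1 by 2.46-fold (2.06 to 2.94), RT1-Da by 2.23-fold (1.94 to 2.57) and Grxcr1 by 2.17-fold (1.91 to 2.45), Ctss by 1.97-fold (1.87 to 2.08) and Zfand2a by 2.34-fold (1.88 to 2.93), and RatNP-3b, at least 579-fold, Defa5, at least 376-fold, and Np4, at least 249.7-fold, again from a single PBS cell. Single cells held 37.7% of RT1-Db1 and 33.7% of RT1-Da among the PBS UMIs, and 45.5% of RT1-Db1 and 35.5% of RT1-Da among the MPSS UMIs. A single PBS cell held 24.8% of Cd74. Cd74, the class II invariant chain, was found in 11.1% (7.79 to 15.1) of PBS and 5.51% (3.59 to 8.02) of MPSS microglia at 1000 UMIs, against 1.32% and 0.478% of oligodendrocytes. The alarmin S100a9 was found in 0.326% and 0.441% of microglia and in 0 of 228 and 0 of 418 oligodendrocytes, which allows up to 1.605% and 0.879%.

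Thinning left out 3 and 3 microglia, 4 and 3 phagocytes and 33 and 35 oligodendrocytes of PBS and MPSS. Median depths were 11476 and 12463 UMIs in microglia, 12759 and 13644 in phagocytes and 10858 and 11851 in oligodendrocytes. Without thinning, Cd74 was in 33.2% and 21.9% of microglia and 6.51% and 5.298% of oligodendrocytes, S100a9 in 3.23% and 2.63% and 4.98% and 0.221%, and Fkbp5 in 17.8% and 33.03% of phagocytes and 19.9% and 30.2% of oligodendrocytes. The higher genes of microglia were Cyp2d3 by 2.33-fold (1.95 to 2.804), RT1-T24-4 by 1.98-fold (1.76 to 2.22), Tgfb1 by 1.93-fold (1.72 to 2.16) and Hpgds by 1.97-fold (1.64 to 2.38). Also higher were Il33 by 1.904-fold (1.57 to 2.33), Taf10 by 1.77-fold (1.57 to 2.01), Snx20 by 1.76-fold (1.49 to 2.09), Rgs2 by 1.66-fold (1.51 to 1.83) and Hsdl2 by 1.69-fold (1.42 to 2.02). Hpgds makes prostaglandin D2 and Il33 is an alarm cytokine.

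Macrophages and monocytes lay mostly in clusters 3 and 4. Cluster 18 held 13.3% of them with PBS and 6.36% with MPSS, and cluster 12 10.7% and 13.7%. The interferon response median was 0.32 (0.23 to 0.60, percentile 99.99), with Mx1 by 2.21-fold (1.58 to 3.12) and Irf7 by 2.25-fold (1.59 to 3.24), and that of MHC class II presentation -0.11 (-0.25 to -0.03, percentile 10.5). The higher were Ly6e by 2.88-fold (2.46 to 3.38), Taf10 by 2.27-fold (2.004 to 2.58), Lyve1 by 2.22-fold (1.83 to 2.701) and Ccl4 by 1.81-fold (1.68 to 1.94). Also higher were Tgfb1 by 1.78-fold (1.58 to 2.01), Hacl1 by 1.74-fold (1.49 to 2.04), Snx20 by 1.79-fold (1.48 to 2.18), Sdf2l1 by 1.603-fold (1.502 to 1.71) and Tmem165 by 1.71-fold (1.45 to 2.03). The direction turned for Lyve1, to a log2 ratio of -0.90 with each library clustered alone, and for Tmem165, to -1.15 with thinning. The lower were Serping1 by 5.11-fold (4.66 to 5.605), Mmp7 by 8.05-fold (6.099 to 10.8), Rsrp1 by 2.55-fold (2.25 to 2.902), Cxcl14 by 2.42-fold (2.21 to 2.65) and S100a4 by 2.24-fold (2.06 to 2.42). Lower too were Lpl by 2.33-fold (2.03 to 2.67), Fxyd2 by 2.23-fold (2.002 to 2.49), Mt3 by 25.2-fold (17.3 to 38.3) and Cxcl13 by 5.08-fold (3.97 to 6.56), with Nppb, at least 183-fold lower, wholly from a single PBS cell. Single cells held 35.6% of Mt3 and 94.6% of Cxcl13 among the PBS UMIs, and 87.8% of Cxcl13 among the MPSS UMIs. Ccl4 is a chemokine, Mmp7 a metalloproteinase and Lpl the lipoprotein lipase. Glycolysis was -0.25 (-0.33 to -0.13, percentile 0.18) and complement -0.22 (-0.32 to -0.15, percentile 0.38).

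The interferon response median was also above 0 with MPSS in the other classes, less firmly in T and NK cells and fibroblasts. The median was 0.78 (0.54 to 0.96, percentile 100) in oligodendrocytes, with Isg15 by 5.22-fold (2.401 to 13.5) and Rtp4 by 2.05-fold (1.54 to 2.77), and 0.84 (0.65 to 1.68, percentile 100) in Schwann cells, where 8 of 17 were at least 2-fold higher. It was 0.40 (0.02 to 0.72, percentile 99.3) in T and NK cells and 0.20 (0.05 to 0.54, percentile 99.3) in fibroblasts, and 0.29 (-0.08 to 0.78) and 0.11 (-0.00303 to 0.54) without the highest cell, intervals that reach both sides of 0. In oligodendrocytes cholesterol synthesis was low, -0.42 (-0.53 to -0.27, percentile 0), with Hmgcs1 by 2.64-fold (2.26 to 3.09) and Cyp51 by 1.45-fold (1.32 to 1.600), immediate early genes high, 0.56 (0.52 to 0.61, percentile 100), with Fosb by 1.84-fold (1.700 to 2.000) and Egr2 by 2.103-fold (1.57 to 2.86), and the myelin list -0.12 (-0.14 to -0.09, percentile 0.265). The genes named by size were higher for Gadd45g by 2.47-fold (2.29 to 2.66), Taf10 by 2.61-fold (2.26 to 3.03) and Ybx1-ps3 by 2.25-fold (1.83 to 2.799), and lower for Trh by 3.08-fold (2.397 to 3.98), C1qtnf9 by 2.901-fold (2.29 to 3.69) and Car2 by 2.097-fold (1.83 to 2.399). Single cells held 63.3% of Trh and 28.6% of Isg15 among the PBS UMIs, and 31.4% of Trh and 35.3% of Isg15 among the MPSS UMIs. With thinning the log2 ratio of Isg15 was -0.87. Ybx1-ps3 can share reads with its parent gene. In Schwann cells Nnat by 10.3-fold (6.67 to 16.9), Isg15 by 20.7-fold (6.94 to 102), Oas1a by 36.1-fold (6.27 to 1443) and Fam183a by 17.8-fold (4.75 to 149.6) were higher and Fabp7 by 2.92-fold (2.51 to 3.395), Calca by 2.22-fold (1.66 to 2.97), Ganab by 2.25-fold (1.53 to 3.31) and Ybx3 by 2.12-fold (1.56 to 2.87) lower. The direction turned for Nnat, to log2 ratios of -1.53 with doublets left out and -0.45 with no cell filter, for Fam183a, to -0.36 with doublets left out, and for Fabp7, to 1.02 with each cell named alone and 0.46 with no cell filter. No direction was read for these 3. Single cells held 42.9% of Nnat, 62.6% of Fabp7 and 29.1% of Calca among the PBS UMIs, and 35.3% of Nnat, 34.1% of Isg15 and 29.2% of Fam183a among the MPSS UMIs. Isg15 rested on 3 PBS UMIs, Oas1a rested on 1 PBS UMI and Fam183a rested on 2 PBS UMIs. The myelin list was 0.33 (0.05 to 0.61, percentile 99.9) there, or -0.16 with each cell named alone. In T and NK cells Taf10 by 3.01-fold (1.71 to 5.56), Glipr1 by 1.97-fold (1.23 to 3.22), Lgals9 by 1.79-fold (1.22 to 2.66) and Lag3 by 1.79-fold (1.11 to 2.96) were higher and Gzma by 16.7-fold (6.24 to 63.3), Dnaja1 by 3.16-fold (2.36 to 4.29), Lgals1 by 3.09-fold (2.23 to 4.34) and Tubb5 by 2.76-fold (2.11 to 3.65) lower. Single cells held 72.7% of Gzma, 50% of Lag3 and 28.4% of Tubb5 among the PBS UMIs. Their T and NK effector list was 0.18 (-0.06 to 0.40, percentile 95.04) and cell cycle -1.71 (-2.48 to -0.84, percentile 0), or -1.56 at the floor. In fibroblasts Hmox1 by 4.96-fold (3.61 to 6.95), Reg3a by 5.47-fold (3.55 to 8.79), Ndufa4l2 by 4.07-fold (3.05 to 5.52) and Postn by 3.19-fold (2.496 to 4.104) were higher and Ca3 by 18.7-fold (11.3 to 33.3), Ube2c by 41.00-fold (15.6 to 153), Cdk1 by 22.4-fold (10.5 to 56.8) and Pi16 by 5.63-fold (5.05 to 6.28) lower. Single cells held 83.3% of Reg3a, 28.6% of Ndufa4l2, 81.5% of Ca3, 45.9% of Ube2c, 44.1% of Cdk1 and 29.2% of Pi16 among the PBS UMIs, and 29.5% of Hmox1, 41.4% of Reg3a, 41.3% of Ndufa4l2, 28.6% of Cdk1 and 32.8% of Pi16 among the MPSS UMIs. The matrix list was 0.01 (-0.10 to 0.07, percentile 69.5), with Acta2 by 15.7-fold (5.78 to 59.9) lower, and cell cycle -0.98 (-1.59 to -0.79, percentile 0). Single cells held 98.04% of Acta2 among the PBS UMIs, and 50% of Acta2 among the MPSS UMIs. Without its highest cell the log2 ratio of Acta2 was 0.70. Over members free of background the cell cycle medians of T and NK cells and fibroblasts were -1.23 (-2.05 to -0.55) and -1.78 (-2.48 to -1.17).

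**Figure D4:**
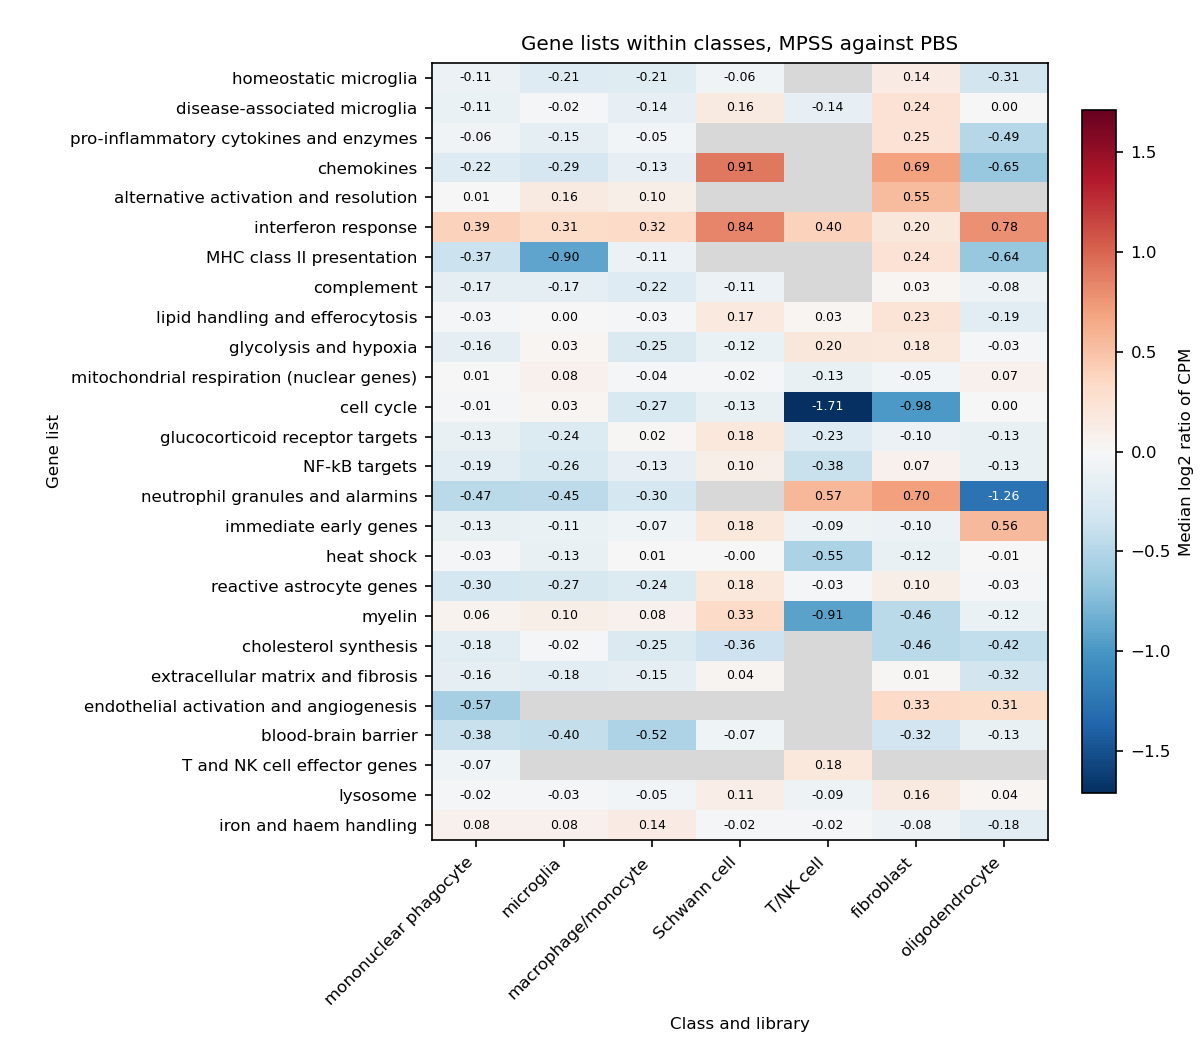
Each cell of the grid is the median log2 ratio of CPM of a gene list (lines of the grid) in 1 class, MPSS against PBS, 1 library each. Red is higher with MPSS, grey has under 5 measured members, and the interferon response list was above 0 in each class drawn, from 0.20 in fibroblasts to 0.84 in Schwann cells.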

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

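All tests of the 3 patterns below were chosen only after the result was seen. Some list medians had one sign at one time point and the other sign at another, with 1 library each, and these differences were not tested. In microglia the interferon response was -0.83 at day 3 and 1.12 at day 7. In endothelial cells glycolysis and hypoxia was 1.04 at day 1 and -0.34 at day 7, immediate early genes were -1.22, -0.52 and 0.31 at days 1, 3 and 7, and cholesterol synthesis 0.60, -0.58 and -0.66. In ependymal cells immediate early genes were 0.21 at day 3 and -0.33 at day 7, and in neutrophils cell cycle genes 0.76, -0.72 and 0.49. Gene names that the day 3 and day 7 tables lack, unused in the comparisons, held 2325 intact and 4864 day 1 UMIs.

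Against intact, 47 of 4993 genes were at least 2-fold higher and 13 lower in all 8 pairs of class and day. All 100 simulated draws, of counting error only and sharing the intact library, gave 0. Free RNA from phagocytes is argued against for the 40 higher members chosen for 25% or more of the phagocyte level in endothelial cells. That choice favours high ependymal percentages too. Their median was 128% (lowest 30.4%), against up to 6.68% for 8 microglia markers (days 3 and 7) or 7.64% for 9 (day 3). For the other 7, at a median of 9.296%, it cannot be told apart from their own expression: Cxcl2, Il1b, Lgals1, Spp1 and Wfdc17 lay within 2 times the highest marker, Cebpb and Fam49b above, at 41.9% and 19.9%. By the median alone it would fit. Of the lower members, 61.5% (31.6 to 86.1) have pseudogene or predicted-gene names, against 2.68% of eligible genes, which for these goes with reads assigned differently in the intact library. P2ry12, Selplg and Tmem119 stood at 2.39%, 1.91% and 1.97% of the phagocyte level in intact ependymal cells, so free RNA of microglia is open for them. With 1 intact library, its properties and an effect of injury cannot be told apart for the higher members. At day 7, 68 genes were higher against intact in 3 classes and 17 against day 3.

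Few cells were named ependymal at day 1. Astrocyte-named cells of that library held the ependymal markers at a median of 25.3% of the intact ependymal level, against 0.205% in endothelial cells, and another setting named 495 ependymal cells. Both go with ependymal cells placed among astrocytes by the naming. Loss of these cells in the tissue or in capture was not tested.

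The interferon response median was above 0 with MPSS in every class measured. Free RNA from phagocytes is argued against in oligodendrocytes, where list members stood at a median of 79.1% of the phagocyte level and microglia markers at most at 9.89%. A few cells with many UMIs are argued against as the whole cause in phagocytes, microglia, Schwann cells and oligodendrocytes, where the medians without the tenth of cells with the most list UMIs were 0.29, 0.37, 0.76 and 1.06. For macrophages, T and NK cells and fibroblasts, at 0.20, -0.0709 and -0.00656, few cells cannot be told apart from a wider difference, as these intervals reach both sides of 0. A difference between the 2 libraries that the injection did not make cannot be told apart from an effect of MPSS with 1 library each. Of 14 lists measured in all 6 classes, 1 had 1 sign in all, and cholesterol synthesis and blood-brain barrier genes were lower in all 5 classes that measured them.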

How the results depend on the processing

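Members free of background and the highest cell left out were chosen only after the results were seen. With 1 library per group, no paired analysis or leaving out of a replicate was possible. Over all alternatives 522 of 632 shares, 1524 of 1954 list medians and 3139 of 3985 gene ratios stayed within the counting interval of the reported value, and 17 medians and 18 gene ratios had the opposite sign beyond it. Homeostatic and disease-associated medians of phagocytes, and the interferon, MHC class II and glucocorticoid medians with MPSS, kept their sign under each alternative run. TMM and median-of-ratios scaling shift all genes of a comparison alike, which is why medians moved together there. For the other values below the cause was not tested. With ranking pseudocounts of 1 and 50 CPM the named sets kept 3 to 19 and 2 to 19 genes. Depth limits shares of cells with a UMI: 38 of 44 moved without thinning.

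With each library clustered alone: the phagocyte share 28.8% (intact), 47.6% (PBS) and 38.3% (MPSS), homeostatic microglia in phagocytes -3.20, -2.49 and -1.76 at days 1, 3 and 7, Arg1 4.66 (phagocytes day 7), MHC class II presentation -2.62 (phagocytes MPSS), Np4 3.91 (phagocytes MPSS), Lyve1 -0.90 (macrophages MPSS). With each cell named alone: the phagocyte share 58.9% (day 1), 71.6% (day 3), 67.8% (day 7), 50.9% (PBS) and 48.6% (MPSS), Mcpt8 -0.96 (neutrophils day 7), glucocorticoid receptor targets -0.072 (phagocytes MPSS), Np4 3.81 (phagocytes MPSS), myelin -0.16 (Schwann cells MPSS), Fabp7 1.02 (Schwann cells MPSS). With the stricter cell filter: the phagocyte share 52.2% (PBS) and 49.4% (MPSS). With Leiden resolution 0.5: the phagocyte share 50.7% (PBS) and 48.5% (MPSS). With TMM scaling: homeostatic microglia in phagocytes -2.81, -1.89 and -1.07 at days 1, 3 and 7, disease-associated microglia in phagocytes 1.56, 2.17 and 3.02 at days 1, 3 and 7, lysosome 0.21 (phagocytes day 1), MHC class II presentation 0.099 (phagocytes day 7), glucocorticoid receptor targets 0.094 (phagocytes day 7), immediate early genes 0.22 (phagocytes day 7), iron and haem handling 0.30 (phagocytes day 7). With median-of-ratios scaling: homeostatic microglia in phagocytes -2.81, -1.87 and -1.05 at days 1, 3 and 7, disease-associated microglia in phagocytes 1.56, 2.19 and 3.03 at days 1, 3 and 7, lysosome 0.21 (phagocytes day 1), interferon response 0.00397 (phagocytes day 3), MHC class II presentation 0.12 (phagocytes day 7), glucocorticoid receptor targets 0.11 (phagocytes day 7), immediate early genes 0.24 (phagocytes day 7), iron and haem handling 0.32 (phagocytes day 7). With the mean over cells: homeostatic microglia in phagocytes -3.38, -2.23 and -1.47 at days 1, 3 and 7, lysosome 0.0086 (phagocytes day 1), Mpo -0.13 (neutrophils day 3), interferon response 0.30 (phagocytes MPSS). With each cell thinned to 1000 UMIs: homeostatic microglia in phagocytes -3.30, -2.18 and -1.40 at days 1, 3 and 7, Elane -0.0025 (neutrophils day 3), interferon response 0.17 (phagocytes MPSS), MHC class II presentation -0.52 (phagocytes MPSS), glucocorticoid receptor targets -0.076 (phagocytes MPSS), Tmem165 -0.54 (phagocytes MPSS) and -1.15 (macrophages MPSS), Isg15 -0.87 (oligodendrocytes MPSS). With a total without mitochondrial and ribosomal protein genes: disease-associated microglia 1.36 (phagocytes day 1), lysosome 0.0093 (phagocytes day 1), homeostatic microglia -1.58 (phagocytes day 7). With no filter on low genes: iron and haem handling -0.11 (phagocytes day 1), MHC class II presentation -0.52 (phagocytes MPSS), glucocorticoid receptor targets -0.042 (phagocytes MPSS). With members free of background: disease-associated microglia 2.13 (phagocytes day 3), pro-inflammatory cytokines and enzymes -0.39 (phagocytes day 3), cell cycle -0.12 (microglia day 7). With the highest cell left out: Arg1 0.0496 (phagocytes day 7), Acta2 0.70 (fibroblasts MPSS). With no filter on cells: MHC class II presentation -0.54 (phagocytes MPSS), Fabp7 0.46 (Schwann cells MPSS), Nnat -0.45 (Schwann cells MPSS). With cycling clusters left out: Np4 3.82 (phagocytes MPSS). With doublets left out: Fam183a -0.36 (Schwann cells MPSS), Nnat -1.53 (Schwann cells MPSS).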

Other observations

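The comparisons of macrophages and monocytes between injured libraries were chosen only after the results were seen. Day 3 against day 1, mostly of clusters 3 and 4 against cluster 2, gave medians of -2.45 (-2.67 to -2.33, percentile 0) for chemokines, -1.81 (-1.92 to -1.72, percentile 0) for the interferon response, -1.75 (-2.01 to -1.61, percentile 0) for pro-inflammatory genes, -1.87 (-1.93 to -1.79, percentile 0) for alternative activation, 2.44 (2.16 to 2.63, percentile 100) for cell cycle and 0.95 (0.93 to 1.08, percentile 100) for lysosome. Day 7 against day 3 gave -1.06 (-1.16 to -0.97, percentile 0) for glycolysis and hypoxia, -0.998 (-1.08 to -0.82, percentile 0) for cell cycle, 0.86 (0.72 to 1.05, percentile 100) for complement and 0.75 (0.70 to 0.95, percentile 100) for NF-kB targets. Taf10 was higher with MPSS in phagocytes (2.02-fold), oligodendrocytes (2.61-fold) and T and NK cells (3.01-fold).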
